A study of Mus musculus with 18 samples.

How the data were processed

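Agilent 2-colour arrays of 9 mice, each measured on 2 arrays with the dyes exchanged against the same reference male, were analysed from the deposited scanner files. Per the file headers, the authors scanned 1 array per file with Feature Extraction 10.7.1.1, which subtracted background, detrended each array spatially and normalised the dyes with a linear (not lowess) method. Per the file headers, LogRatio is the log10 of red (Cy5) over green (Cy3), and the processed signals are intensities after those steps. The deposited value table of the series holds log2 ratios made by the authors from the same arrays. Set against the scanner values, it runs as reference over animal on every array (correlation −1.00) with a shift per array of 0.00 to −0.02 after turning the sign, and its column medians lie between 0.00 and 0.01. Its software is not given in the sources used here.

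Each file has 120997 features, of which 6563 are controls and 114434 are probe spots of 110417 probes. Control spots and spots flagged as outliers (114 to 337 per array) were left out, no spot was saturated, and the spots of 1014 probes printed more than once were averaged. The array with 337 flagged spots was that of progeny 6 in Cy5, and every other array had at most 186. The log2 ratio was taken from the processed signals, which carry the scanner's own dye normalisation, and turned to animal over reference on each array with the dyes of the labels. Each array was then centred on its median, with no loess or quantile step. Arrays of 1 dye orientation correlated across probes at 0.39 to 0.70. The 2 orientations of 1 animal correlated at −0.49 to 0.15, which shows a dye effect per probe that cancels in their mean. The 2 arrays of an animal were averaged as 1 replicate. Median processed signals lay near 1000 on every array, and the number of arrays limits the precision.

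Intervals were called per animal with an interval score, the sum of log2 ratios over the noise times the square root of the number of probes. The noise was the robust SD of differences between neighbouring probes. Probes were 45 to 60 bp long, and some 3-probe calls spanned only 104 to 127 bp, so their probes overlap. Differences between overlapping probes cancel what they share, so the noise may be too low there. The score also treats probes as independent, so a call of 3 overlapping probes holds less than 3 independent measurements. A call needed a score of at least 6, at least 3 probes, an absolute mean of at least 0.25, the same sign with at least 0.15 on both arrays, and no gap over 100 kb. Single intervals were scored up to 200 probes, and calls of 1 sign at most 2 probes apart were joined. On simulated steps of 0.5 and −0.8 placed in the dye half-difference tracks of all 9 animals over 110417 probes, 98.3% to 100.0% of steps of 3 to 20 probes were found. Smaller steps, such as the median of 0.33 in the progeny-only regions, were not simulated. Overlapping calls of 1 direction were merged across animals, and each animal's value is the mean over the probes called in the most animals. A region was progeny-only if a progeny was called and both parents stayed below 0.5 of the carriers' median in the carriers' direction. A parent shifted the other way met this rule. It was counted as shared by parent and progeny if both generations were called, as parent-only if a parent was called and every progeny stayed below 0.5 of the carriers' median, and as undetermined otherwise (43 regions). These names describe calls, not proven transmission. Of the 215 regions, 60 overlapped a region of the other direction.

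For tests, neighbouring probes at most 2 kb apart formed clusters of at least 5 probes, set by position alone. limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg at 0.05) tested the family mean against 0 over 9 animals, 7 progeny against 2 parents, and the 7 progeny against each other in a moderated F test on 14 arrays with dye orientation as a covariate. On simulated data with 200 of 1394 clusters shifted by 0.25, each of the 3 tests recovered 100.0%, with 9, 9 and 6 false calls. With shifts of 0.1 they recovered 100.0%, 95% and 99%, with 17, 14 and 6 false calls, which is above the nominal 5% of calls in the first 2 tests. For the F test the simulated array noise was the SD of the dye half-difference, which is smaller than that of 1 array. All noise was drawn independently per cluster with no slide effect, and the second test shifted all 7 progeny alike. The simulated rates hold only for such data and may be better than those of the arrays. The comparison of mother and father counts clusters and has no test. Calls and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

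The alternatives, fixed before the data were examined unless stated otherwise, were these. Other values were normexp (offset 50) with median centring, centring on the mode, probes well above background on every array (1168 probes fewer), and the deposited value table. Other call rules were a score of 8, an absolute mean of 0.4, 5 probes, no gap limit, a single dye orientation, and merging on 1/2 of the shorter call. Other cluster gaps were 0.5 kb and 10 kb. Each animal was left out in turn, and slide was a random block or the F test was taken within slides. Slides were read from the array identifiers: both parents shared 1 slide and the progeny lay on 4 others, so generation and slide go together. A further 2 alternatives were added after seeing the data: calls of at least 10 probes, and leaving out progeny 5 and 6 together. Normexp was to use mean signals, but the scanner's median signals and median backgrounds were used in their place.

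The rule for named regions, fixed before the data were examined, takes the largest absolute carrier medians: 8 progeny-only, 8 shared, 5 called in all animals (none existed) and 4 parent-only regions. It adds the 5 clusters with the lowest adjusted p in each limma test and the 3 clusters with the largest difference between mother and father. Fixed gene lists (antigen receptor loci, known copy number polymorphisms of C57BL/6, chemosensory families, testis repeats and DNA repair genes) could not be matched. The files name no genes, and the gene table used here is on another assembly. The study's text also mentions an earlier genome-wide screen and TaqMan copy number assays, which were not analysed here.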

Results

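Array comparative genomic hybridisation was used to look for copy number differences in 1 family of C57BL/6JNrs mice. The family held a father, a mother and 7 progeny. Tail DNA of each animal was hybridised together with DNA of 1 reference male of the same colony, first with the animal in Cy3 and then with the dyes exchanged, which gave 18 arrays. The 2 arrays of an animal share their DNA and were averaged, so there was 1 father, 1 mother and 7 progeny (n = 1, 1 and 7). The question named in the study's title is whether continuous gamma irradiation of the father at 1 mGy per day for 400 days changes copy number in the next generation. The labels conflict on this male: the title describes exposed males, whereas the design text calls the father of this family non-irradiated. No unexposed family was part of this series, so no effect of dose could be compared here.

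The array was a second, custom array that covered places where an earlier screen of the same family, with autosomal probes about 2 kb apart, had shown aberrant probes. It held 110417 distinct probes, of which 110366 lay on the 19 autosomes, 48 on X and 3 on Y. Most probes (96.2%) lay in 1394 clusters with a median of 102 probes over 10525 bp and a median spacing of 82 bp. Since the probes were chosen for apparent aberration in these animals, a call on this array is not independent evidence of one. Between 99.3% and 99.6% of the spots of each array were well above background in both channels. Single-probe noise of the averaged log2 ratio (animal over reference) was 0.052 ± 0.005 (SD, n = 7 progeny). All positions are in mouse build mm9, the build of the file headers. The files pair no probe with a gene and the gene table used here belongs to another assembly, so regions are given by position and no gene is named.

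The sex chromosome probes were read first, as a check of the parents' labels against a male reference. The mean log2 ratio over the X probes was 0.91 in the mother and −0.01 in the father. Over the 3 Y probes it was −2.36 in the mother and −0.03 in the father. Both parents therefore had the X and Y signal that their labels require. Every interval call described below was autosomal, as the X and Y probes lie too far apart for one. The labels do not give the sex of the progeny, and their values are only listed. The X probe means of progeny 1 to 4 lay between −0.02 and 0.00, and those of progeny 5, 6 and 7 were 0.85, 0.86 and 0.91. The Y probe means of progeny 5, 6 and 7 were −1.99, −2.12 and −2.54.

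The number of interval calls per animal was compared next, to ask which animals carried copy number differences from the reference. Progeny 6 had 115 calls, of which 94 were gains, and progeny 5 had 65 calls, of which 53 were losses. The other progeny had 5, 20, 9, 24 and 21 calls, in the order of progeny 1, 2, 3, 4 and 7. The mother had 41 calls, of which 35 were gains, and the father had 9, of which 7 were losses. The median over the 7 progeny was 21 calls. Most calls were short: 110 of the 115 calls of progeny 6 and 36 of the 41 calls of the mother held fewer than 10 probes. As a background, the same caller was run on the difference between the 2 dye orientations divided by 2, a track in which copy number cancels. That track gave 16 to 40 calls per animal, and progeny 5, progeny 6 and the mother had more calls than their own track. After the mean track of all 9 animals was subtracted, which removes the dye effect common to them, it gave 0 to 12 calls, and every animal had more calls than its own track. The 2 kinds of track are not alike. Before subtraction the single-probe noise was 0.084 to 0.097 in the dye track and 0.045 to 0.058 in the averaged ratio. Shifts common to all animals were not subtracted from the averaged ratio. The counts carry no p-value. With calls of at least 10 probes, a limit chosen after seeing the data, 2 calls were left in the father, 5 in the mother and a median of 3 per progeny.

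**Figure D1:**
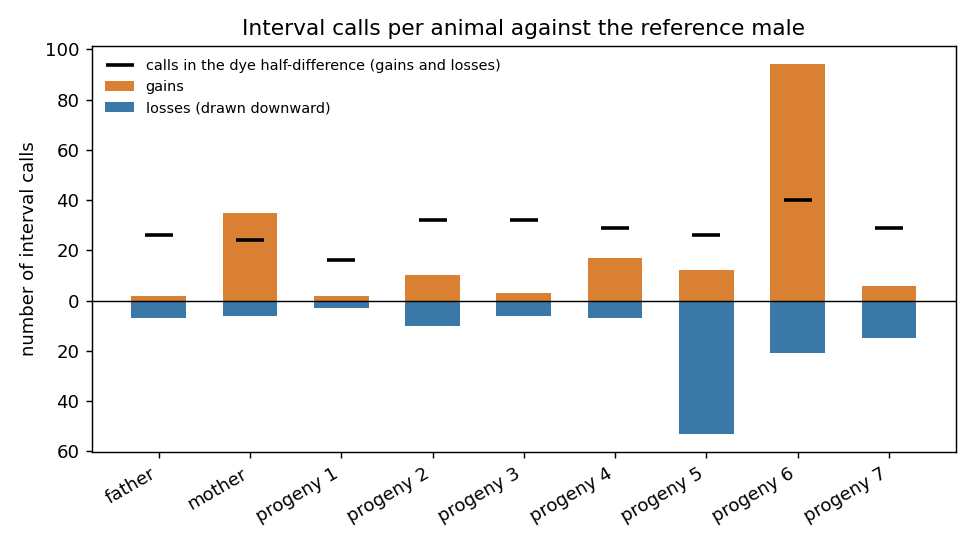
Number of interval calls (vertical axis) in each of the 9 animals (horizontal axis), with gains drawn upward and losses downward from 0. Black dashes give all calls, gains and losses together, in the dye half-difference of the same animal, which ranged from 16 to 40. The 94 gains of progeny 6 and the 53 losses of progeny 5 exceed those of every other animal.

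The 309 calls fell into 215 merged regions, which were sorted by which generation carried them. A loss on chromosome 19, positions 39751064 to 39842043, was called in the mother and in all 7 progeny and not in the father. Over the 16 probes shared by the most calls, the mean log2 ratio was −1.54 in the mother, −0.47 ± 0.07 in the progeny (SD, n = 7) and −0.05 in the father. The progeny lay between −0.40 and −0.57. In 15 of these 16 probes the mother was below the progeny mean, and in 15 every progeny was below the father. At 3 of the 4 probes where the mother was below −2 the signal of at least 1 array was not well above background, so her values there are not exact. Over the other 13 of the 16 probes the mean was −1.05 in the mother, −0.37 ± 0.06 in the progeny (SD, n = 7) and −0.03 in the father. The mother's 2 arrays differed from their mean by 0.09 over the 16 probes, which is far smaller than her distance from the progeny.

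**Figure D2:**
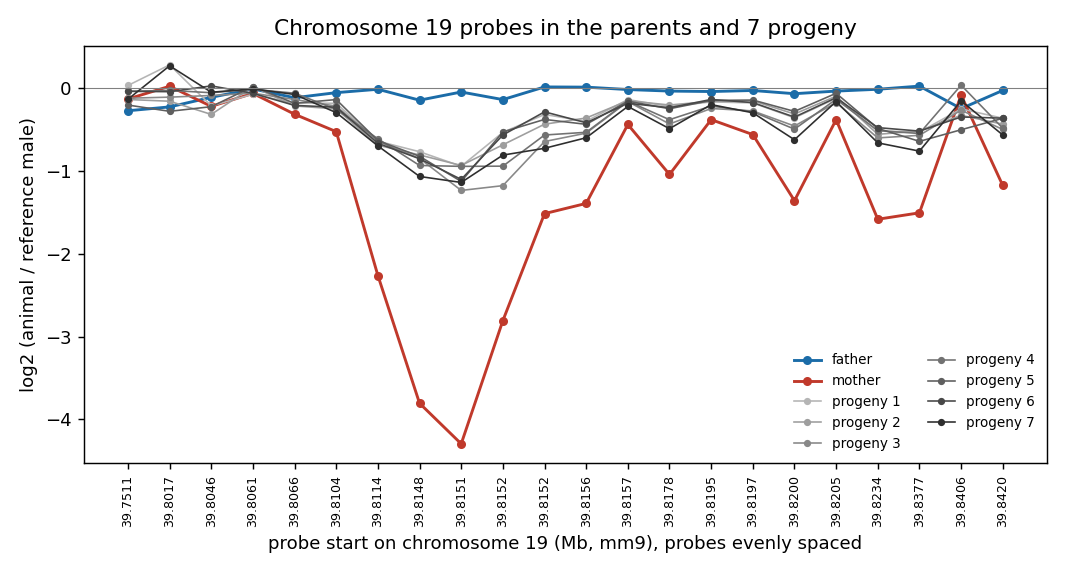
Log2 ratio of animal over reference male (vertical axis) at the 22 probes of the chromosome 19 region, in order of position (horizontal axis, evenly spaced). Each line is 1 animal; the mother reaches −4.30, and the 7 progeny lie between her and the father at each probe from 39811372 to 39837677 but not at several of the others.

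Another set of regions was called in exactly the mother and progeny 5, 6 and 7. The longest was a loss on chromosome 3, positions 25416456 to 25447997, with 130 probes. Its mean log2 ratio was −1.91 in the mother and −1.86, −1.84 and −1.95 in progeny 5, 6 and 7, while the father was at −0.03 and progeny 1 to 4 lay between −0.07 and 0.00. A loss on chromosome 2, positions 111694136 to 111694677, over 6 probes, was at −0.96 in the mother, at −0.86, −0.90 and −0.88 in the same 3 progeny, and between 0.00 and 0.08 in the other 5 animals. Smaller shifts with the same carriers were losses on chromosome 14 at 61810539 to 61820885 (mean of the 4 carriers −0.32, other animals −0.02) and on chromosome 10 at 45067424 to 45068898 (−0.33 and −0.03). Gains with these carriers were on chromosome 10 at 52261314 to 52265658 (0.27 and 0.00) and on chromosome 18 at 4885069 to 4885481 (0.33 and −0.01). The last 4 of these regions fall outside the rule for named regions and were chosen after their values were seen. In all 6 regions the values of the 4 carriers did not overlap those of the other 5 animals. These 4 animals are also the ones with raised X probe means and low Y probe means.

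**Figure D3:**
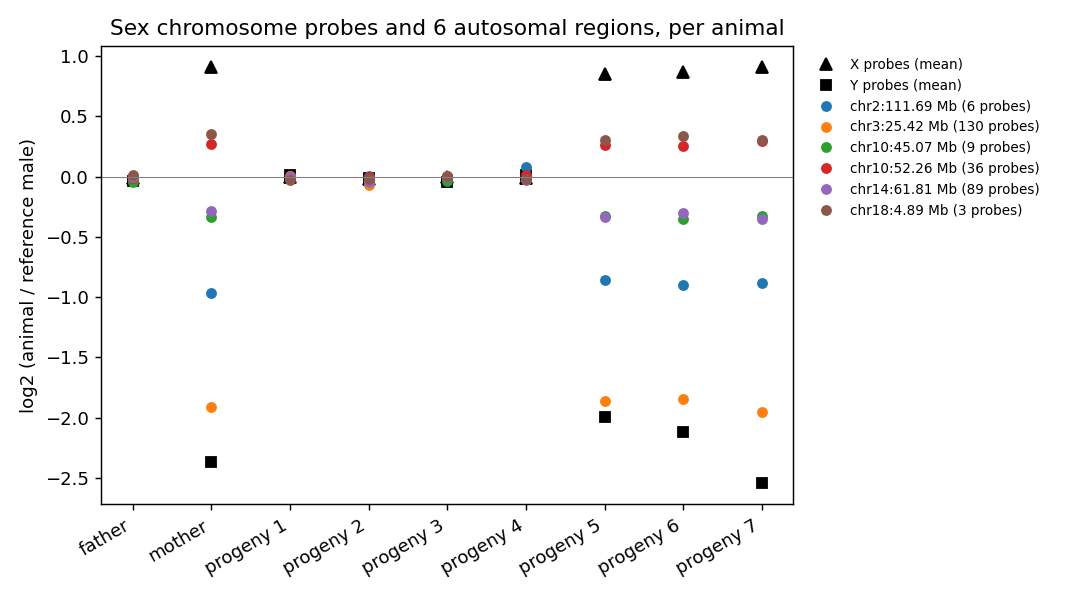
Mean log2 ratio of animal over reference male (vertical axis) of the X probes, the Y probes and 6 autosomal regions in each of the 9 animals (horizontal axis); each point is the mean over the probes of 1 track. The mother and progeny 5, 6 and 7 part from the other 5 animals in every track, with the chromosome 3 region at −1.84 or lower in each of them.

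In all, 25 regions, 14 gains and 11 losses, were called in a parent and in at least 1 progeny in the same direction. Of the 8 with the largest shifts, 3 are described above. A gain on chromosome 10, positions 97112448 to 97112551, over 3 probes, was called in 7 animals and lay at 0.36 ± 0.05 over all 9 (SD). A loss on chromosome 14, positions 54078363 to 54182285, was called in the father and 6 progeny, and over its 5 shared probes lay at −0.35 ± 0.03 over all 9 animals (SD). The other 3 had 3 shared probes each. A gain on chromosome 2 at 70084179 to 70084314 was at 0.43 in the father and 0.81 in progeny 7. The median of its 2 carriers fell from 0.62 to 0.13 with normexp background correction, and no value was left over the probes well above background. A gain on chromosome 6 at 60888093 to 60888827 was at 0.38 in the mother and 0.40 in progeny 6. A loss on chromosome 17 at 79954249 to 79954660 was at −0.35 in the father and −0.71 in progeny 5, whereas the mother stood at 0.41 there, and with normexp its carriers' median went from −0.53 to −0.35. Across the 25 regions the median was 3 shared probes and the median absolute log2 ratio was 0.32. No region was called in all 9 animals, although the chromosome 10 gain and the chromosome 14 loss had the same sign in each. With calls of at least 5 probes 12 such regions were left, and with normexp background correction 11.

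Regions called in progeny while both parents stayed below the limit in the carriers' direction bear on the question of new copy number changes in the offspring. A parent shifted the other way also met this rule, so the parents were not always near the reference. At 30 of the 32 losses of progeny 5 alone, for example, the mother was above 0. There were 142 of them, 89 gains and 53 losses, and most were short. The median was 3 shared probes and the most was 13, no carriers' median reached an absolute log2 ratio of 0.8, and the largest was 0.70. Among those with at least 5 shared probes the largest was 0.54, and among those with at least 10 it was 0.36. The gain on chromosome 6 described below had 3 shared probes, but was called over 5 probes in progeny 6, at 0.90. A single animal carried 130 of them: 79 were called in progeny 6 alone, of which 76 were gains, and 34 in progeny 5 alone, of which 32 were losses. Progeny 1, 2, 3, 4 and 7 carried 1, 6, 2, 3 and 5 alone. Without progeny 6 the count was 66, and without progeny 5 and 6 together, a step chosen after seeing the data, it was 23.

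Of the 8 progeny-only regions with the largest shifts, 7 were gains led by progeny 6. On chromosome 5 at 111557907 to 111558033 progeny 6 was at 0.70 and the other 6 progeny between 0.11 and 0.28, with the father at 0.11 and the mother at 0.00. On chromosome 10 at 45060313 to 45060493 progeny 6 was also at 0.70 and the other progeny between 0.08 and 0.28. On chromosome 6 at 25696261 to 25697462 progeny 6 was at 1.03 and progeny 1, also called, at 0.32. Progeny 2, 4 and 5, not called there, were higher than progeny 1, at 0.44, 0.42 and 0.40. Progeny 3 and 7 were at 0.27 and −0.05, the father at 0.22 and the mother at −0.07. On chromosome 16 at 79107801 to 79107984, over only 2 shared probes, progeny 6 was at 0.98 and progeny 4, also called, at 0.40. Progeny 2, not called there, was at 0.49. Progeny 1, 3, 5 and 7 were at 0.15, 0.25, 0.32 and 0.03, the father at 0.24 and the mother at 0.03. The gains on chromosome 3 at 77637702 to 77637893, on chromosome 14 at 71875229 to 71875458 and on chromosome 7 at 98641145 to 98641256 were at 0.63, 0.58 and 0.57 in progeny 6. The exception was a 3-probe gain of progeny 3 on chromosome 4 at 30873784 to 30874184, at 0.56, where its 2 arrays lay 0.30 above and below that mean. At that place the father was called as a loss at −0.32. With normexp this gain fell to 0.10, and no value was left over the probes well above background. The 76 gains of progeny 6 alone had a median of 0.34 in progeny 6, 0.12 in progeny 2, 0.11 in progeny 4 and 0.12 in progeny 5. It was 0.05, 0.07 and 0.03 in progeny 1, 3 and 7, 0.03 in the father and −0.003 in the mother. The 32 losses of progeny 5 alone had a median of −0.36 in progeny 5 and 0.24 in the mother. The 5 progeny-only regions with at least 10 probes, picked out after their values were seen, were all losses. They lay on chromosome 2 at 137987497, on chromosome 5 at 128284424, on chromosome 12 at 108353481 and on chromosome 14 at 92060554 in progeny 5, and on chromosome 3 at 75876148 in progeny 6. Their log2 ratios were between −0.28 and −0.36, and the mother was above 0 at each.

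Only 5 regions, 4 gains and 1 loss, were called in a parent with no progeny near the parent's value. The loss was in the father on chromosome 4, positions 102943011 to 102944696, over 8 probes. It was at −0.32 in the father, with his 2 arrays 0.01 from that mean, at −0.03 in the mother and at 0.03 ± 0.03 in the progeny (SD, n = 7). The named gains were in the mother, on chromosome 18 at 72611911 to 72612163 (0.42), on chromosome 13 at 87758497 to 87759034 (0.39) and on chromosome 2 at 137987807 to 137988331 (0.36). The fourth, also in the mother and outside the naming rule, was on chromosome 5 at 150253328 to 150253719 (0.32). At 3 of these 4 gains progeny were called as losses: progeny 5 and 6 at the chromosome 18 place (−0.44 and −0.38), progeny 5 over the longer chromosome 2 loss named above (−0.30) and progeny 6 at the chromosome 5 place (−0.28). The chromosome 13 gain stood at 0.14 with normexp and at −0.016 over the probes well above background. Without progeny 4 this class held 28 regions.

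Shifts shared by the whole family against the reference were tested per probe cluster. A block on chromosome 14 was lower than the reference in all 9 animals. From 53759070 to 54259481, 10 clusters had family means between −0.37 and −0.22, and 4 clusters inside this span, from 54006065 to 54063633, were between −0.01 and 0.03. The 5 clusters with the lowest adjusted p all lay here, and each was below 0 in 9 of 9 animals. The cluster at 53759070 to 53765083 was at −0.37 ± 0.009 (SE, n = 9 animals, limma adjusted p = 2.05e-11). The clusters at 54197219 to 54201387 and 54232556 to 54244753 were at −0.24 ± 0.006 and −0.28 ± 0.007 (limma adjusted p = 2.05e-11 and 3.06e-11). Those at 54134515 to 54135450 and 53957204 to 53998997 were at −0.33 ± 0.009 and −0.23 ± 0.006 (limma adjusted p = 3.42e-11 for both). A merged region outside the naming rule started before these clusters, at 53410263, and ran to 53998706. It was called in the mother and progeny 3, 4 and 7. Over its 278 shared probes all 9 animals lay between −0.31 and −0.23. A shift in all animals against 1 reference animal can lie on either side, and the test leaves out the reference's own spread. The 9 animals are parents and their own offspring, so they are not independent of each other. The SE and p-values of this test therefore describe how repeatable a shift was within this family. They do not extend to other mice of the colony.

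Over all 1394 clusters, limma called 78 at an adjusted p under 0.05, 22 higher and 56 lower than the reference. Only 12 of them had an absolute mean of at least 0.2, all of them lower: the 10 on chromosome 14 and 2 inside the chromosome 19 region. The other 66 were at most 0.20 in size, 22 higher and 44 lower. The 10 clusters on chromosome 14 were called under each scaling, with slide as a random block and when any single animal was left out. The total was less stable, with 46 clusters (9 higher) with slide as a random block, 49 (7 higher) with centring on the mode, and 292 (12 higher) on the deposited value table. It was 161 without the mother and between 16 and 36 when any 1 of the 7 progeny was left out.

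**Figure D4:**
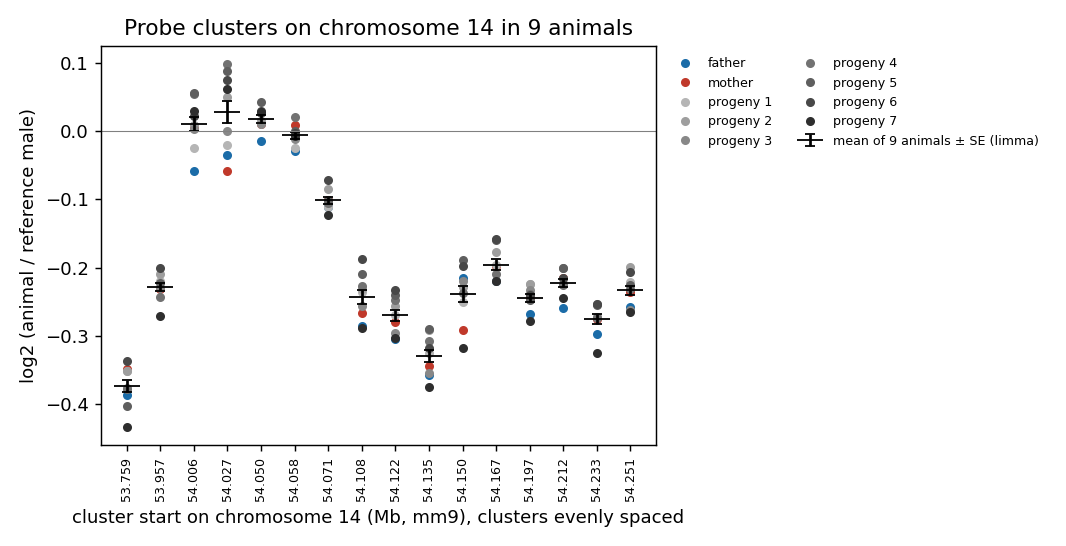
Mean log2 ratio of animal over reference male (vertical axis) in 16 probe clusters of chromosome 14, in order of position (horizontal axis, evenly spaced). Points are the 9 animals and dashes the family mean with its standard error; every animal is below 0 in 12 clusters, and the means of the 4 clusters from 54006065 to 54063633 lie near 0.

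Progeny and parents were compared to ask whether any cluster differed between the generations. In limma none of the 1394 clusters passed an adjusted p of 0.05, and 73 had an unadjusted p under 0.05. The closest was a cluster of 8 probes on chromosome 11, positions 12962063 to 12962893, at −0.09 ± 0.03 in the progeny (SD, n = 7) and 0.04 in the parents, a difference of −0.12 ± 0.022 (SE, limma adjusted p = 0.236). Next were clusters on chromosome 4 at 14757159 to 14760819 and on chromosome 3 at 148251093 to 148256334, with progeny minus parents of −0.06 and −0.05 (limma adjusted p = 0.645 for both). The clusters on chromosome 14 at 54027267 to 54028049 and on chromosome 4 at 10303559 to 10303888 were at 0.10 and 0.09 (limma adjusted p = 0.735 for both). Father and mother are 2 animals on 1 slide, and the progeny were on 4 others. The progeny get their copies from these 2 parents, so inherited differences leave the 2 means close. A new change in 1 progeny would widen the spread and move the mean of 7 little. The lack of calls therefore does not speak against new changes in single progeny.

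Without the father, limma called 2 clusters, both in the chromosome 19 region, where the progeny were above the mother (differences of 1.74 and 0.50). Without the mother it called 2: the chromosome 19 cluster at 39814846 to 39815758, where progeny minus father was −0.58, and a cluster on chromosome 4 at 102941859 to 102945847 around the father's loss, at 0.15. In both fits the remaining parent is assumed to vary like the progeny.

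Differences among the 7 progeny were tested against the noise between the 2 arrays of an animal, to find places where siblings differ. The chromosome 3 cluster at 25411960 to 25447997 differed most, with a range of 1.44 over the progeny (limma F test, adjusted p = 3.45e-12). It was followed by the clusters on chromosome 14 at 61810539 to 61820885 (range 0.31, limma adjusted p = 6.61e-07) and on chromosome 10 at 52261314 to 52268423 (range 0.23, limma adjusted p = 3.12e-06). In each of these, progeny 5, 6 and 7 stood on one side and progeny 1 to 4 on the other. A cluster of 40 probes on chromosome 15, positions 3877947 to 3883951, was at 0.16 in progeny 7, 0.09 in progeny 4 and 0.07 in the mother, and between −0.05 and −0.02 in the other 5 progeny and the father (range 0.20 over the progeny, limma adjusted p = 0.0045). The fifth was on chromosome 10 at 52281871 to 52287944 (range 0.09, limma adjusted p = 0.0056).

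In all, 170 clusters passed, but only 6 had a range of at least 0.2 and 33 a range of at least 0.1 among the progeny. The error here is technical, so the test says that animals differ and not that a group does. Within slides, where progeny 1 and 2, 3 and 4, and 5 and 6 share a slide, 4 clusters passed, all with ranges of at most 0.11. This fit compared only the 2 progeny of a slide and did not compare progeny 7. Differences between progeny 5, 6 and 7 and progeny 1 to 4 could therefore not pass, so the lower count does not speak against them. They lay on chromosome 4 at 97513100 to 97523059, on chromosome 10 at 52281871 to 52287944, on chromosome 11 at 74128905 to 74130010 and on chromosome 18 at 85235773 to 85243719. Normexp correction left 25, and omitting 1 progeny at a time left 80, 162, 50, 74, 58, 82 and 97 clusters in the order of progeny 1 to 7.

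Mother and father were compared as 2 single animals, with no p-value. In 4 clusters their difference was at least 0.25 with the same sign on both dye orientations, and the mother was lower in 3. In the chromosome 19 cluster at 39814846 to 39815758 mother minus father was −2.32, and in the one at 39817777 to 39820504 it was −0.70. In the chromosome 3 cluster at 25411960 to 25447997 it was −1.38. The mother was higher by 0.25 in the chromosome 10 cluster at 52261314 to 52268423. The first 3 of these also passed a threshold of 0.4.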

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

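All tests of explanations in this part were chosen after the result was seen, except that of probe length, which was set before. Across 44 sets of 7 progeny values, 10 values stood apart from the other progeny by Dixon's criterion, which chance does in about 1 of 20 sets. That rate does not apply to the 6 regions among them, which were named for their large shifts.

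The first pattern is the many short calls of progeny 6 and progeny 5. Progeny 6 stood apart with 94 gains (next highest 17) and progeny 5 with 53 losses (next highest 21), as did the values of progeny 6 at gains on chromosomes 5, 10, 3, 14 and 7 (0.70, 0.70, 0.63, 0.58 and 0.57). Whether the losses of progeny 5 are new copy number changes was not decided. At the 32 losses it carried alone the mother stood at 0.24. The upper end of the central 95% of 10000 random runs of probes was 0.013. Her value has the opposite sign to the losses, so an offset common to the arrays would not give them. The progeny-only rule also left out places where the mother was low, unlike the random runs. A slide effect shared by progeny 5 and 6 was not decided either. At the 76 gains of progeny 6 alone the median of progeny 5 minus that of progeny 2, on another slide, was −0.0057 (95% bootstrap interval −0.018 to 0.011). Gains also called in progeny 5 were not among these 76, so the choice of places itself kept progeny 5 low. Sequence-dependent hybridisation is a candidate explanation, since the probes of the 76 gains averaged 56.3 bp, at percentile 98.3 of random runs (mean 55.3 bp), where length stands for base composition. New changes of progeny 6 cannot be told apart from an offset common to the arrays: the other 6 progeny had a median of 0.085 at these gains, but the places were chosen for high values against 1 shared reference, and 0.26 (0.24 to 0.27) was left in progeny 6 once the others' mean was taken off, close to the call limit of 0.25.

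The second pattern is the set of autosomal regions carried by the mother and progeny 5, 6 and 7, the animals with raised X and low Y probe values. Autosomal transmission from the mother is argued against at the chromosome 3 region. Progeny 5, 6 and 7 lay there at −1.84 or lower, below the −1 that a full copy from the father would leave. It stays open at the chromosome 2 loss, where their lowest value was −0.90, close to 1 of 2 copies lost. Of the 5 regions besides that on chromosome 3, only this 1 was near the value of 1 copy lost or gained. The other 4 had carrier means of −0.33, −0.32, 0.27 and 0.33. These values argue against 1 whole copy lost or gained there, and other changes passed on by the mother were not tested. The slides are argued against too, since mother and father shared a slide and differed by −1.88 at the chromosome 3 region. Sequence shared between these places and a sex chromosome was not tested, as no genome sequence was used here, and stays open: that 6 regions had exactly these 4 carriers, against at most 2 for any other of the 126 sets of 4 animals, only restates the pattern. By a looser criterion, non-overlapping values whose means differ by at least 0.15, this set parted 10 regions and the set of progeny 2, 4, 5 and 6 parted 33.

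The third pattern is the chromosome 19 loss. A change on both of the mother's chromosomes, passed on once to each progeny, may account for it. The progeny mean differed from the mean of the parents' linear ratios by 0.055 (log2) in the median of 16 probes, and by at most 0.15 in 13 of them. Any change passed on in this way would give that, so it does not single out a full loss. Each progeny, at −0.40 to −0.57, lay above the −1 that 1 of 2 copies lost would leave. The mother was at −1.05 over the 13 probes well above background on every array. At the 4 probes where she was below −2, 3 of them not well above background on an array, the progeny averaged −0.83. Her 3 Y probes, whose sequence a female lacks, ran from −4.79 to −0.37. A probe for absent sequence can thus read far short of a full loss. Whether both her copies were fully lost over these probes is therefore not decided. A fault of the mother's arrays is argued against by 7 of 7 progeny, on other slides, at −0.25 or lower. A segment that differs in sequence without a loss of copies cannot be told apart from one with a loss. In the mother 15 of the 16 probes were at −0.25 or lower, and ratios do not separate the 2 cases. All 3 readings rest on 1 mother.

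Among the other values that stood apart, progeny 7 was at 0.81 in the gain on chromosome 2 at 70084179, where the next progeny was at 0.27, but with normexp background correction the carriers' median there fell from 0.62 to 0.13. Progeny 7 was also lowest in the chromosome 14 clusters at 54197219 (−0.28, next −0.25) and 54232556 (−0.33, next −0.27).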

How the results depend on the processing

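The main counts were 9 calls in the father, 41 in the mother and a median of 21 in the progeny, and 142 progeny-only, 25 shared and 5 parent-only regions. In the same order, normexp gave 3, 20 and 7 calls, with 11 shared and 3 parent-only regions. An absolute mean of 0.4 gave 1, 7 and 2 calls and 47, 5 and 1 regions. At least 5 probes gave 4, 20 and 7 calls and 37, 12 and 2 regions, and at least 10 probes (chosen after seeing the data) 2, 5 and 3 calls and 5, 7 and 0 regions. Without a second dye orientation, arrays with the animal in Cy5 gave 50 calls in the father, 84 in the median progeny and 56 shared regions. Those with the animal in Cy3 gave 18, 83 and 36 calls, 19 parent-only regions and 1 region called in all animals, against 0. Probes well above background gave 3 parent-only regions, and over them the mother's chromosome 13 gain changed sign to −0.016. Without single progeny, progeny-only regions numbered 66 (without progeny 6) to 142, and parent-only regions 5 to 28 (without progeny 4). Without progeny 5 and 6 together, chosen after seeing the data, 23 progeny-only regions were left. Of the clusters, family versus reference (main 78) gave 49 with centring on the mode, 292 on the deposited table, 328 with gaps of 0.5 kb, 46 with slide as a random block, 13 without progeny 5 and 6, and 16 to 161 without single animals. The differences among progeny (main 170) gave 25 with normexp, 57 with gaps of 0.5 kb, 4 within slides, 22 without progeny 5 and 6, and 50 to 162 without single progeny. Differences between slides cannot show in the fit within slides. Progeny versus parents gave 0 in every setting but those without the father or the mother (0 to 2 over single animals). Mother minus father (main 4) gave 12 with gaps of 0.5 kb, where 3204 clusters were formed. The deposited table was kept with its own centring, and its column medians of 0.00 to 0.01 (reference over animal) place clusters slightly lower. Of its 292 family clusters, 280 were lower. The median absolute family mean in the main setting was 0.008, so the smallest shifts are of the size of that offset. The cause of the other changes was not tested. All 12 family clusters of at least 0.2 were called under each scaling and with the slide block, and the 10 on chromosome 14 also without any single animal. Of 78 values of the 20 named regions under 4 alternative scalings and filters, 19 moved by more than the spread between dye orientations and 1 changed sign. With normexp the gains on chromosome 2 at 70084179, on chromosome 4 at 30873784 and on chromosome 13 at 87758497 fell from 0.62, 0.56 and 0.39 to 0.13, 0.10 and 0.14. Signal over background limits few probes, 1168 of 110417. No paired analysis was possible because the groups share fewer than 2 replicate numbers.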

Other observations

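The chromosome 14 block that was lower in all 9 animals also differed in depth along its length. The cluster at 54070627 to 54084627 had a family mean of −0.10 and the cluster at 54167369 to 54183007 one of −0.20, between the clusters near 0 and those at −0.22 or lower. Since each animal shows the block against the same reference male, the values do not tell a gain in the reference from a loss in the family. The family means of −0.37 to −0.22 also lay above the −1 that 1 of 2 copies lost would leave. Readings other than these 2 were not tested, and the antigen receptor loci of the fixed lists could not be matched to this block.

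At the 32 losses called in progeny 5 alone, the median was −0.36 in progeny 5, −0.16 in progeny 6, −0.13 in progeny 2, −0.10 in progeny 3 and −0.10 in the father, and 0.20 in progeny 4 and 0.24 in the mother. The mother was above 0 at 30 of the 32. In a test chosen after these calls were seen, their probes averaged 57.9 bp, longer than in all 10000 random runs of as many probes. At the 76 gains called in progeny 6 alone, the mean of the other 6 progeny was above 0 at 72.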
